A study of Homo sapiens with 6 samples.

How the data were processed

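Gene expression was measured on Affymetrix Human Genome U133 Plus 2.0 arrays in OVCA433, a cell line of high-grade serous ovarian cancer. Of 6 arrays, 3 came from untreated control dishes and 3 from dishes given fresh medium with versican. Versican is a large chondroitin sulfate proteoglycan of the extracellular matrix. Per the labels' protocols, medium was changed 24 hours after seeding, RNA was taken 48 hours after treatment, 10% fetal bovine serum was in the growth medium, and 100 ng of total RNA went into each labelled cRNA. The dose and the form of the versican protein were not given in the sources used here. The treatment protocol also speaks of transfection at harvest, which the sample descriptions do not, and all samples were taken as the titles name them. Series text calls the samples of a group independent. Nothing says that they came from separate days or cultures. P-values of single genes therefore measure the spread between these samples, which may be partly technical.

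The authors deposited 1 table of intensity values, which are probe set signals on a linear scale made with MAS5, per the submitters' processing notes. The MAS5 version, its target and its detection calls were not given in the sources used here. The 2% trimmed mean of the deposited values was 500.1 on each array, so each array carries a scaling factor of its own. MAS5 subtracts mismatch probes, and its log values are noisy at low signal. No further normalization was applied for the main results. There were 54675 probe sets, of which 62 were AFFX controls. GEO's platform annotation paired 41097 probe sets with 1 gene symbol and 1801 with several, and 11721 non-control probe sets were unnamed here. Symbols were updated through the gene identifier for 41043 of the 41097, and 54 kept their older symbol. No genome was used, so no coordinates are given. Scan dates and array batches were not given in the sources used here.

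Values were analysed as log2(signal + 16) with R 4.3.3 and limma 3.58.1. Fold changes are on that scale and understate the change of dim genes. Each of 19775 genes was represented by its probe set with the highest mean log2 value over the 6 arrays. The 9887 genes in the upper 50% by mean were tested, whose lowest mean signal was 201. The fit was lmFit with the group as the only term, then eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of single genes come from this limma test. On simulated data with the spread of these arrays and 9887 genes, 66 or 67 genes were changed by each size, with noise independent between genes. There the fit found 97.0% of genes changed by 1 on the log2 scale, 67.2% of those changed by 0.5 and 25.4% of those changed by 0.25. It called 11 of 9687 unchanged genes. In the real data 41.6% of tested genes were called, which makes the adjustment less strict, so these shares do not carry over to them. The number of arrays limits the precision.

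Before the data were examined, 24 gene lists with 558 genes were fixed, of which 516 genes were measured by a probe set with 1 symbol. The remaining list genes were not analysed here. Lists with at least 3 tested members (21) were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 21 lists. Camera compares a list's genes with all other tested genes. At the preset correlation its p-values, for lists and families alike, rest mainly on the number of genes and the spread between them. They do not measure the spread between samples. The tests with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance, were alternatives. The list of study genes (CD44, MMP9, HMMR) was written from knowledge of the study, which may have chosen them on these samples.

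Genes named in the text were fixed by rule before the data were examined. They are the 12 largest changes in each direction among called genes whose groups do not overlap, VCAN and the study genes, 4 members with the smallest p of each called pathway list and 2 of each other pathway list. Any other gene was chosen after its values were seen. Alternatives were pseudocounts of 1 and 64, no filter, the upper 25% of genes, quantile, median and cyclic loess normalization, no trend, a robust trend, array weights, the mean of a gene's probe sets, leaving out _x_at and _s_at probe sets, every probe set as its own unit, the replicate number as a block, and leaving out each array in turn. The 3 same-numbered pairs of arrays deviated together with correlations of 0.119, -0.019 and -0.090, so the numbers were not taken to pair samples. Values of 3 against 3 arrays outside the limma fit were compared by exact permutation, which cannot give p under 0.10.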

Results

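Transcript levels were compared between OVCA433 cells kept for 48 hours in fresh medium with versican and untreated control cells, with 3 arrays per group. Whether the control dishes were also given fresh medium was not established here. Median signal over all probe sets lay between 62.8 and 75.8 per array. On the 9887 tested genes, arrays of one group correlated at 0.993 to 0.995 and arrays of different groups at 0.969 to 0.972. The first principal component held 75% of the variance and separated the groups. The 3'/5' signal ratio of ACTB was 1.27 ± 0.035 (SD, n = 3) in control and 1.25 ± 0.013 (SD, n = 3) in versican arrays. That of GAPDH was 0.969 ± 0.016 and 0.962 ± 0.023 (SD, n = 3 each), so neither ratio differed by more than its spread. Signals of the 3 control probe sets for 18S ribosomal RNA were 1.15-fold higher with versican (exact permutation test, two-sided, p = 0.10, the smallest that 3 against 3 allows).

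The first question was which genes differed between treated and untreated cells. Of 9887 genes, 2081 rose and 2036 fell with versican, 41.6% in all. Most changes were small: the median absolute log2 fold change of called genes was 0.37, and 112 genes rose and 99 fell by at least 2-fold. Groups did not overlap for 5160 genes, 52.2%, where chance gives 10%. Of the called genes, 2361 had a further tested probe set. For 1255 of these a further probe set was called in the same direction, and for 46 one was called in the opposite direction.

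MMP9, a secreted gelatinase that degrades basement membrane collagen, rose more than any other tested gene. Its signal went from 1342 ± 61 to 10508 ± 451 (SD, n = 3 each), 7.75-fold (log2 2.95, SE 0.05, adjusted p = 9.9e-10). CD44, the main cell surface receptor for hyaluronan, rose 2.63-fold (log2 1.39, SE 0.05, adjusted p = 1.1e-07), from 4247 ± 190 to 11186 ± 269 (SD, n = 3 each). HMMR, a hyaluronan-binding protein that is also a component of the mitotic spindle, rose 2.74-fold (log2 1.45, SE 0.09, adjusted p = 1.1e-06). All 3 study genes therefore rose, also when adjusted over the list alone (3 of 3), but the list may have been chosen on these samples and is not independent evidence. The list as a whole was called higher (camera adjusted p = 9.4e-05), and adjusted p = 0.138 with an estimated correlation. CD44's probe sets disagreed in size: the one used had the highest signal, and the other tested ones rose by between 1.32-fold and 2.05-fold. HMMR's second probe set rose 2.47-fold. MMP9 had 1 probe set.

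The VCAN transcript, which encodes versican itself, was abundant in control cells (signal 3172 ± 253, SD, n = 3) and rose 1.39-fold in the versican group (log2 0.48, SE 0.07, adjusted p = 0.00061). Its 5 probe sets gave 1.32-fold to 1.51-fold, and in the fit of every probe set the smallest of these did not pass (adjusted p = 0.051). If versican was added as protein, as the series title says, this transcript does not check the treatment. The wording of the treatment protocol on transfection leaves that point open.

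**Figure D1:**
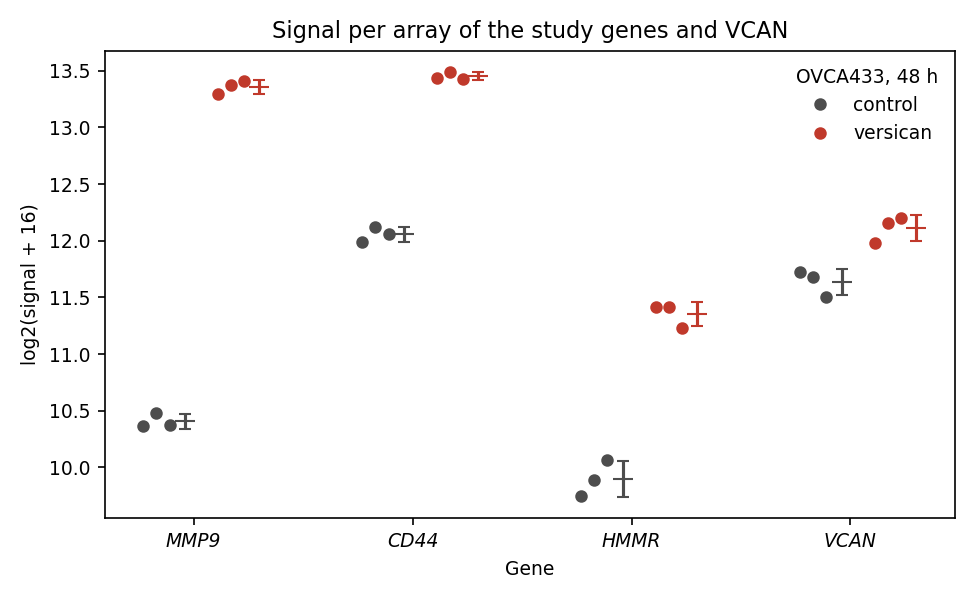
Signal of MMP9, CD44, HMMR and VCAN on each array, as log2(signal + 16) on the vertical axis, for 3 control arrays (grey) and 3 versican arrays (red). Points are arrays, and the dash with a bar beside them is the mean ± SD; the versican arrays lie above all control arrays for each gene, with the widest gap for MMP9 (log2 2.95) and the narrowest for VCAN (0.48).

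After MMP9, the 11 largest increases were in NTM, DCLK1, RGCC, TMEM200A, PRSS2, MIR146A, HMGA2, XDH, TMEM158, PTX3 and ANKRD22. NTM, a neural cell adhesion molecule, rose 4.56-fold (log2 2.19, SE 0.12), and DCLK1, a microtubule-associated kinase, rose 4.49-fold (log2 2.17, SE 0.32). RGCC, a cell cycle regulator, rose 4.03-fold and TMEM200A rose 3.91-fold. HMGA2, a chromatin protein of embryonic and tumour cells, went from 1428 ± 41 to 5113 ± 34 (SD, n = 3 each), 3.55-fold. XDH, xanthine dehydrogenase, rose 3.29-fold, TMEM158 3.19-fold, PTX3, a secreted pentraxin of innate immunity, 3.02-fold, and ANKRD22 3.0-fold. PRSS2, a trypsinogen, rose 3.67-fold, measured by probe sets that can cross-hybridize with near-identical trypsinogen genes. The probe set that the annotation names MIR146A rose 3.63-fold. It reads a primary transcript and not the mature microRNA. Further tested probe sets rose less for NTM (2.38-fold), XDH (2.31-fold), PRSS2 (2.66-fold) and ANKRD22 (2.21-fold). Adjusted p-values of these 11 genes ran from 1.6e-08 for HMGA2 to 0.00048 for DCLK1.

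The 12 largest decreases were led by MAP1LC3C, an autophagosome protein of the LC3 family, whose signal went from 2905 ± 564 to 396 ± 65 (SD, n = 3 each), 7.06-fold lower (log2 -2.82, SE 0.14, adjusted p = 4.1e-07). TIMP3, a matrix-bound inhibitor of metalloproteinases, fell from 1510 ± 137 to 334 ± 21 (SD, n = 3 each), 4.35-fold (log2 -2.12, SE 0.09, adjusted p = 2.0e-07), and its 3 further probe sets fell too (log2 -1.82, -1.75 and -1.50). PSG5, a pregnancy-specific glycoprotein of a family with near-identical members, was 4.85-fold lower, and CLDN11, a tight junction claudin, 4.63-fold lower. AKR1B10, an aldo-keto reductase, was 3.78-fold lower, and SLC2A3, the glucose transporter GLUT3, 3.60-fold lower. GFRA1, a receptor for the neurotrophic factor GDNF, was 3.56-fold lower. Other probe sets changed less for PSG5 (log2 -0.75 against -2.28) and for GFRA1 (-0.90 and -0.80 against -1.83). CLIC3 went from 9635 ± 738 to 2695 ± 99 and PLAC8 from 15161 ± 832 to 4425 ± 177 (SD, n = 3 each), 3.55-fold and 3.42-fold lower. VTCN1, the immune checkpoint ligand B7-H4, TMEM130 and TMEM178A were 3.43-fold, 3.44-fold and 3.40-fold lower.

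**Figure D2:**
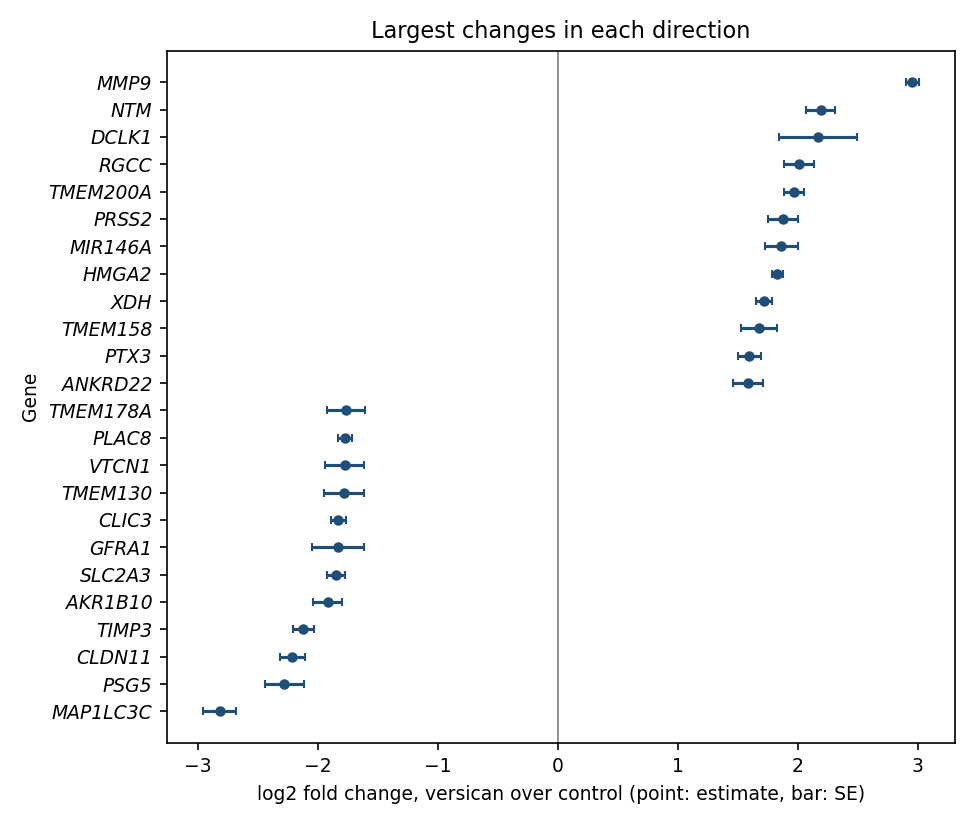
The 12 largest increases and the 12 largest decreases. The horizontal axis is the log2 fold change of versican over control, points are estimates and bars are standard errors; values run from -2.82 for MAP1LC3C to 2.95 for MMP9, and DCLK1 has the widest error (SE 0.32).

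Genes of cell division rose together. All 30 mitosis genes rose, with a median of 2.00-fold (log2 1.0, SD over genes 0.20), and all 30 also passed when adjusted over the list alone. A further probe set of CCNB2, chosen after its values were seen, was called in the opposite direction. They included CENPE and CENPF, kinetochore proteins, at 2.35-fold and 2.21-fold, UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, at 2.10-fold, and BIRC5, survivin, at 2.09-fold. Of 26 tested genes of DNA replication, 24 rose (25 when adjusted over the list alone) and none fell, with a median of 1.75-fold. RFC3, a clamp loader subunit, rose 2.03-fold, RRM2 and RRM1, the subunits of ribonucleotide reductase, 1.89-fold and 1.67-fold, and MCM2, a subunit of the replicative helicase, 1.89-fold. The members that did not pass in the first count were SLBP and CCNE1 (log2 0.14 and 0.25, chosen after their values were seen). Camera called both lists higher (adjusted p = 8.1e-23 for mitosis and 1.3e-15 for replication), and both calls held with an estimated correlation (adjusted p = 0.0068 and 0.034). The 18S ribosomal RNA signal was also higher with versican (1.15-fold, exact permutation test, p = 0.10), but any difference between 2 groups lies in the same arrays. A link between that signal and these genes was not tested.

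Of 23 tested NF-kB target genes, chosen because NF-kB signalling is a subject of the study, 11 rose and 3 fell (the same counts when adjusted over the list alone). CXCL1 and CXCL2, neutrophil-attracting chemokines, rose 2.91-fold and 2.62-fold, their relative CXCL3 (chosen after its value was seen) 2.94-fold, and IL1B, an inflammatory cytokine, rose 2.39-fold. TNFAIP3, which encodes the NF-kB inhibitor A20, rose 2.14-fold. TNFAIP2, ICAM1 and CSF1 fell by 0.92, 0.74 and 0.49 on the log2 scale (chosen after their values were seen). NFKBIA, the classical feedback inhibitor, had a log2 fold change of 0.01 (SE 0.05, adjusted p = 0.93) and was also chosen after its value was seen. Camera called the list higher (adjusted p = 0.010), while its median was only 0.10 and its mean 0.37 on the log2 scale. The adjusted p was 0.288 with an estimated correlation. CXCL1, CXCL2 and CXCL3 are similar in sequence, and sharing of signal between them cannot be separated here.

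Matrix proteases and their inhibitors moved in both directions: 5 of 21 tested genes rose and 8 fell (9 when adjusted over the list alone), and the list was not called (adjusted p = 0.77), with a median log2 fold change of -0.06 and a mean of 0.06. MMP9 and TIMP3 changed most. The other 4 that rose were ADAMTS1, a versican-cleaving protease (log2 1.04, SE 0.08), PLAUR, PLAU and SERPINB5 (0.53, 0.28 and 0.23), all chosen after their values were seen. Besides TIMP3, the proteases CTSL, ADAMTS15, CTSB, ADAM10, CTSD, ADAM9 and ADAM17 fell, with log2 fold changes from -0.27 to -0.16. ADAMTS5, of the same family as ADAMTS1, did not pass (0.13, adjusted p = 0.17). MMP2 and MMP14 had log2 fold changes of -0.06 and -0.07 and did not pass (adjusted p = 0.36 and 0.39, likewise chosen). Among 8 tested genes of hyaluronan and versican binding, 3 rose, namely CD44, HMMR and EGFR (log2 0.36), and HABP4 and HYAL2 fell by 0.48 and 0.19. That list was not called (adjusted p = 0.19). It was called among the upper 25% of genes (0.011), after median centring (0.047) and without _x_at and _s_at probe sets (0.024). CD44 and HMMR, its largest changes (log2 1.39 and 1.45), are study genes that may have been chosen on these samples. These calls are therefore not independent evidence. Of 23 integrin and adhesion genes, 6 rose and 5 fell without a call for the list (adjusted p = 0.68). ITGA6, the laminin-binding integrin subunit alpha 6, rose 2.19-fold and L1CAM, a neural adhesion molecule, 1.52-fold.

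Camera called the list of hypoxia and glycolysis genes lower (adjusted p = 0.0015), with adjusted p = 0.196 with an estimated correlation. Of 26 tested, 16 fell and 2 rose (3 when adjusted over the list alone), with a median log2 fold change of -0.30. SLC2A3 was 3.60-fold lower, PFKFB3, which makes the activator of phosphofructokinase, 2.84-fold lower, ALDOC, a brain-type aldolase, 1.96-fold lower, and P4HA1, a collagen prolyl hydroxylase, 1.48-fold lower. The 2 that rose were the glycolytic enzymes ENO1 and TPI1 (log2 0.37 and 0.19), chosen after their values were seen, as were PGK1 and LDHA, which did not pass (both 0.08, adjusted p = 0.25 and 0.32). The list was not called among the upper 25% of genes (adjusted p = 0.12). P4HA1 did not pass when all probe sets of a gene were averaged (adjusted p = 0.066).

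Camera called the list of TGF-beta response genes lower (adjusted p = 0.0074), with adjusted p = 0.138 with an estimated correlation. Of 22 tested, 9 fell (11 when adjusted over the list alone) and 4 rose, with a median log2 fold change of -0.22. BAMBI, a decoy receptor of the TGF-beta family, was 2.26-fold lower, CDKN2B, the cell cycle inhibitor p15, 1.99-fold lower, TGFB2, a TGF-beta ligand, 1.77-fold lower, and ID1, a helix-loop-helix inhibitor of differentiation, 1.58-fold lower. The 4 that rose were ID2, TGFBI, INHBA and LTBP2, by 0.37, 0.28, 0.26 and 0.14 on the log2 scale, chosen after their values were seen.

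Camera called both the epithelial and the mesenchymal list lower (adjusted p = 0.040 and 0.039), but neither call held, with adjusted p = 0.56 and 0.196 with an estimated correlation. Of 24 epithelial genes 8 fell and 2 rose. MUC1, a membrane mucin, was 2.57-fold lower, ELF3, an epithelial transcription factor, 2.27-fold lower, GRHL2, a regulator of epithelial junction genes, 1.62-fold lower, and CLDN7 1.31-fold lower. CDH1, E-cadherin, had a log2 fold change of 0.00 (SE 0.06) and EPCAM of -0.07 (SE 0.14), and neither passed (adjusted p = 0.98 and 0.71, both chosen after their values were seen). Of 18 tested mesenchymal genes 8 fell and 2 rose. COL1A1, a fibrillar collagen chain, was 1.85-fold lower, LOX, the collagen cross-linking enzyme, 1.75-fold lower, and COL5A1 1.45-fold lower. VIM, the intermediate filament vimentin, rose 1.46-fold, and the other that rose was S100A4 (log2 0.17). The counts were the same when adjusted over each list alone. Without control replicate 2 the epithelial list missed the threshold (adjusted p = 0.11), without control replicate 1 the mesenchymal list did (0.052), and without versican replicate 2 both did (0.057 each). Both were also lost with the mean of probe sets (0.056 and 0.26), where COL1A1 did not pass (0.26). The epithelial call was lost without an intensity trend (0.071), and the mesenchymal call with array weights (0.051), among the upper 25% of genes (0.48) and without _x_at and _s_at probe sets (0.20). Among 10 tested serous ovarian markers, PAX8 and MECOM rose (log2 0.90 and 0.21), and KLK8, CD24, KLK6 and MSLN fell by 1.38, 0.58, 0.56 and 0.30, named after their values were seen. That list was not called (adjusted p = 0.17), but was called lower with the mean of probe sets (0.013). Its other members lay below the filter. WT1 had signals of 8.9 ± 6.0 in control and 27.9 ± 7.7 in versican arrays (SD, n = 3 each). In the same order, EMX2 had 5.3 ± 4.6 and 12.3 ± 11.2, and ESR1 had 52.0 ± 8.8 and 76.2 ± 12.6. KLK7 had 277 ± 15 and 104 ± 13.

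**Figure D3:**
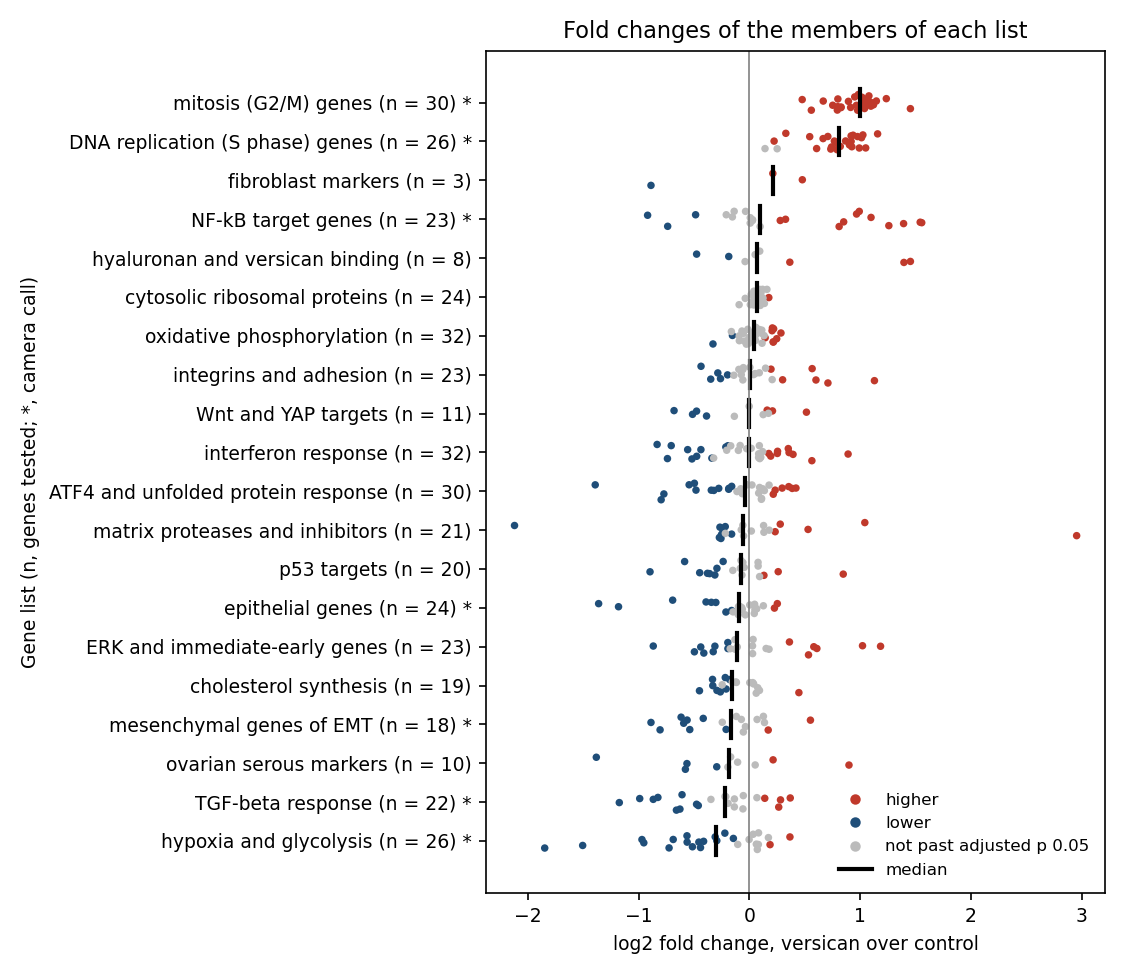
Log2 fold change of versican over control (horizontal axis) for each tested gene of 20 lists, with the number of genes tested beside each name and an asterisk where camera called the list. Red points rose, blue points fell, grey points did not pass adjusted p of 0.05 and black bars are medians; mitosis (median 1.0) and DNA replication genes lie to the right, while hypoxia and TGF-beta genes centre left of 0.

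The remaining lists were not called by camera. Of 23 ERK and immediate-early genes 6 rose and 8 fell (10 when adjusted over the list alone, adjusted p = 0.68), with a median of -0.11 and a mean of 0.04 on the log2 scale. DUSP6, an ERK phosphatase induced by ERK, and FOSL1, an AP-1 subunit, rose 2.27-fold and 2.03-fold. Of 32 interferon-responsive genes 9 rose and 10 fell (adjusted p = 0.55), with IFITM2, an antiviral membrane protein, 1.78-fold lower and PSMB9, an immunoproteasome subunit, 1.67-fold lower. Of 30 genes of the ATF4 and unfolded protein response 6 rose and 12 fell (adjusted p = 0.33). DDIT4, a stress-induced inhibitor of mTORC1, went from 10940 ± 568 to 4153 ± 90 (SD, n = 3 each), 2.63-fold lower, and SLC7A5, an amino acid transporter, was 1.40-fold lower. Of 19 cholesterol synthesis genes 1 rose, PMVK at 1.36-fold, and 8 fell, among them INSIG1 at 1.37-fold (adjusted p = 0.12). Of 20 p53 targets 3 rose and 8 fell (adjusted p = 0.13). GDF15, a stress cytokine, was 1.86-fold lower, while FAS, a death receptor, rose 1.80-fold. With no filter both the cholesterol and the p53 list were called lower (adjusted p = 0.043 each). After cyclic loess both were too (0.049 each), and the p53 list also after quantile normalization (0.050) and without _x_at and _s_at probe sets (0.019). Of 11 Wnt and YAP targets 3 rose and 4 fell (4 and 5 when adjusted over the list alone, adjusted p = 0.55), with AMOTL2 and CCN2 1.43-fold and 1.39-fold lower. Ribosomal protein genes had a median log2 fold change of 0.07, and 1 of 24 rose (0 when adjusted over the list alone, adjusted p = 0.22). Without control replicate 2 this list was called higher (adjusted p = 0.0046). Of 32 oxidative phosphorylation genes 8 rose and 2 fell (7 and 2 when adjusted over the list alone, adjusted p = 0.38). Fry, which does not compare a list with other genes, called 16 of the 21 lists.

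Markers of other cell types were mostly below the expression filter in both groups. Among 13 fibroblast markers only COL1A1, COL6A3 and VCAN were tested. That list was not called (adjusted p = 0.80), with a median log2 fold change of 0.21 and a mean of -0.07. COL1A1 fell, and COL6A3 rose by 0.21 on the log2 scale (SE 0.06). DCN and LUM, abundant in fibroblasts, had control signals of 34.0 ± 14.0 and 96.7 ± 32.2 and versican signals of 40.0 ± 0.9 and 37.5 ± 8.8 (SD, n = 3 each). Of 13 measured leukocyte markers only LAPTM5 was tested, and it rose by 0.31. PTPRC, CD45, had signals of 14.5 ± 1.9 and 25.3 ± 5.8 (SD, n = 3 each). Of 12 endothelial markers EGFL7 and TIE1 were tested and fell by 0.41 and 0.32. Of 10 mesothelial markers MSLN fell, and BNC1 had signals of 399 ± 69 and 414 ± 65 (SD, n = 3 each). LRRN4, below the filter, had signals of 50.1 ± 15.0 and 164 ± 27 (SD, n = 3 each).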

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

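Signals outside the tested genes differed between the groups too. Among probe sets with no gene in the annotation table, 563 of 3285 tested were called (242 higher and 321 lower with versican, 17.1%). The changes with the largest folds among them were 4.76-fold and 3.36-fold higher and 3.64-fold and 3.48-fold lower. Among probe sets with several genes, 316 of 1110 were called (150 higher and 166 lower, 28.5%). Both shares come from the fit of every probe set, with its own filter. They cannot be set against the 41.6% of tested genes that were called. The control probe sets for 18S ribosomal RNA were higher with versican by 0.203 on the log2 scale, with no overlap of the groups.

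The counts were compared with other splits of the 6 arrays into 3 and 3, a test chosen before the data were examined. The 10 possible splits are too few for a share under 0.05. The real split gave 2081 genes higher, 2036 lower and 8 lists, and the highest of the other splits gave 0, 0 and 6. Every other split called at least 2 lists. In each case 1 of the 10 splits, the real one, gave a result as large. Each other split mixes both groups in both arms, so their large difference enters the spread within arms and keeps gene counts low. Part of that difference also stays between the arms and can call lists. The comparison therefore cannot decide on chance.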

How the results depend on the processing

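With the upper 25% of genes, 4943 were tested and 1290 rose and 1131 fell. With every probe set as its own unit, the count corresponding to genes higher with versican was 3715 and that corresponding to genes lower with versican was 3863. Both settings tested another number of units than the main fit, so their counts cannot be set directly against the reported ones. The number of lists called was 2 with an estimated correlation and 16 with fry, and with the other alternatives it lay between 6 and 10. All other alternatives gave gene counts within 1.5 times the reported ones, with the lowest total after median centring (1636 higher and 1382 lower). Leaving out 1 array gave 1680 to 1940 genes higher and 1639 to 1911 lower. With the replicate block, 2030 genes rose and 1943 fell, and 8 lists were called. Same-numbered arrays deviated together with correlations of 0.119, -0.019 and -0.090, and 2 of 6 arrays correlated best with their own number. Among alternatives tested gene by gene, called genes took the opposite direction only with the mean of probe sets (6) and without _x_at and _s_at probe sets (9). With every probe set, 46 called genes had a further one called in the opposite direction. Of 1236 values of the 68 named genes, 1234 kept direction and call. The exceptions were COL1A1 (log2 -0.14, adjusted p = 0.26) and P4HA1 (-0.36, 0.066) with the mean of probe sets. Of the list values, 403 kept their side of the threshold, 19 passed it and 17 lost it, and 5 of the 8 called lists were called under every camera alternative with the preset correlation. The causes were not tested. Dim genes are limited by signal over background, which MAS5 leaves noisy.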

Other observations

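The tests of gene families, of HMMR and of cell density were chosen after the results were seen, and the tests of scaling before. Families were formed from genes that share a symbol root and have at least 6 tested members. Camera with the preset correlation called 16 of 232 such families, and 0 with an estimated correlation (adjusted p of 0.65 or 0.66 for the called families named here). With the root PSMD, mostly subunits of the proteasome's regulatory particle, 11 of 13 rose (median log2 fold change 0.31), and the 2 that did not pass were PSMD10 and an antisense gene. With the root PSMC, which also takes in PSMC3IP, 4 of 6 rose. The further proteasome roots PSMA and PSMB were not called (camera adjusted p = 0.15 and 0.92). Of 7 PSMA genes 3 rose, and of 11 PSMB genes 5 rose and 3 fell. Among those that fell were PSMB8 and PSMB9 (log2 -0.52 and -0.74), which are also on the interferon list. All 7 tested genes with the root CCT, subunits of the cytosolic chaperonin, rose (median 0.29), as did 16 of 21 with the root NUP, mostly nuclear pore proteins (median 0.31, 1 fell). With the roots of mitochondrial ribosomal proteins, 23 of 49 rose for MRPL, which takes in the antisense gene MRPL20-AS1 (not called), and MRPL33 fell, while 15 of 27 rose for MRPS.

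AKR1B10, AKR1C1, AKR1C2 and AKR1C3 fell by 1.92, 1.46, 1.32 and 0.90 on the log2 scale, 4 of 6 tested aldo-keto reductases, and the AKR1C genes are close paralogs whose signals are not separated here. Of 13 genes with the root ALDH, aldehyde dehydrogenases, 9 fell and 2 rose, with ALDH3B1 2.82-fold lower. Of 11 genes with the root HLA, many of them paralogs, 7 fell and none rose, and 1 of the 7 was the antisense gene HLA-F-AS1. The direction of the median of each of the 16 families stayed under quantile normalization and cyclic loess.

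About 2 in 5 tested genes were called, which a difference in scaling between the groups might produce. After cyclic loess, 97.9% of the called genes were called in the same direction, which argues against an intensity-dependent difference in scaling as the whole cause. After median centring, 70.3% were, and 0 in the opposite direction, so whether a gene was called depended in part on the scaling method. Median centring moved the median log2 fold change of all tested genes only from 0.007 to 0.028. The lost calls are thus not shown to come from a scaling difference between the groups. Centring used the median of all probe sets, which lay below the lowest mean signal of a tested gene (201). That median was 75.8 on control 1 but 62.8 and 64.9 on control 2 and control 3. Centring thus also shifted arrays of one group against each other. Whether that shift cost the calls was not tested. The 18 hybridization spike probe sets differed by -0.076 on the log2 scale (SE 0.030), a size that with 2 SE added (0.135) stayed under the median change of called genes (0.37), which argues against a scaling difference that the spikes would show. Effects of dish handling, any difference in medium change included, or of array processing shared by the 3 arrays of a group stay open, since no batch is known here.

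HMMR may have risen simply as one of the mitosis genes. Its change lay 2.9 SD above the mean of the other 29 (0.94, SD 0.18) and its second probe set 2.06 SD above, but the kinesins KIFC1 (log2 1.43) and KIF20B (1.33) lay within 2 SE of it, so a separate rise of HMMR and a rise with mitosis genes cannot be told apart. The bound first used, 2 SD alone, would have excluded the rise with mitosis genes, and the comparison with kinesins was added after that outcome was seen. Cross-hybridization in 1 probe set was argued against by the ratio of 0.898 between the log2 changes of its 2 probe sets, both of which passed.

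All 30 mitosis genes rose while 16 of 26 hypoxia and glycolysis genes fell and 2 rose (adjusted p = 0.196 for the latter list with an estimated correlation), a pattern that fewer cells per dish could produce. YAP targets, which are higher in sparse cells, had a median log2 fold change of -0.262 (8 tested, 0 higher, 4 lower). The set passed the fry test of limma as lower. Fry called 16 of the 21 lists here, and these 8 were taken from the Wnt and YAP list after its values were seen. The test therefore cannot decide on density. The median of the 8 also lay within the SD over the genes (0.32), a bound that was itself added after the outcome was seen, so density stays open. Cell counts at harvest were not used here. An effect of versican on the cell cycle is a hypothesis that stays open, untested beyond these samples.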
